A study of Mus musculus with 4 samples.

How the data were processed

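The series holds 4 RNA sequencing libraries, 2 of the unirradiated and 2 of the irradiated CAF group, from Dll1-mCherry MMTV-PyMT mammary tumours. Per the labels' protocols, tumours were digested with collagenase and hyaluronidase, treated with a PDGFRa antibody, and RNA was DNase-treated, selected for poly(A) tails and made into libraries with a kit that does not mark strand. Reads of a gene and of an antisense or overlapping partner can therefore not be told apart. Per the submitters' processing notes, STAR 2.5, HTSeq 0.6.1 and DESeq2 were used with the mm10 genome, and their settings and the annotation release are not given in the sources used here. The deposited files hold the authors' whole-number counts per gene, not normalized, for 54532 genes with coordinates, and per the file headers a gene length in bases. Of these genes, 54495 identifiers occur in GENCODE release M21 on GRCm38, and 98.3% of them have identical coordinates there. Reads of near-identical copies could be split between them or left uncounted, as the authors' counting settings are not given. This concerns globins, immunoglobulin constant genes, histones, MHC class I genes, Hspa1a and Hspa1b, and ribosomal protein pseudogenes, so values of single members are uncertain.

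Groups were taken from the labels. Total counts ranged from 13011489 to 23763830 per library. The 2 libraries of a group were compared by a chi-square statistic per gene over genes with at least 20 summed counts. The median was 2.11 times that expected from counting alone for the unirradiated pair and 2.14 times for the irradiated pair, against 28.1 to 30.5 times between groups. Each library was kept as a replicate, but these values do not show whether A and B are separate animals or technical repeats. The labels give no batch or animal, so a batch that follows the groups cannot be told apart from irradiation. A rank test of single values with 2 against 2 libraries cannot reach an exact two-sided p below 0.333, and none was used.

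Counts were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood fit and F-test, R 4.3.3), with Benjamini-Hochberg adjustment over 15961 genes and a threshold of 0.05, and all adjusted p-values of genes are from this test unless another is named. Standard errors were derived as the absolute log2 fold change over the square root of F. The fit left 2 residual degrees of freedom and gained 60.0 prior degrees of freedom by pooling across genes. Camera from limma 3.58.1 compared each of 41 gene lists with all other tested genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Lists were matched by symbol, so the 2 gene identifiers that share the symbol Aldoa both count as members. With the preset correlation 15 lists were higher and 8 lower. With a correlation estimated per list 0 passed, 8 had an unadjusted p under 0.05, and the smallest adjusted p was 0.213. That setting rests on the 2 residual degrees of freedom, so it had little power. A call lost there does not show that a list was unchanged. For 38 of the 41 lists the counts of higher and lower members were the same adjusted over the list alone. The functions were tested on counts simulated for this comparison over 15961 genes, from the real means and library sizes and the fitted common dispersion. Simulated genes varied independently, and 200 genes and 2 lists were changed, whereas 66.4% of the real tested genes were called. The outcome therefore checks the code and does not give the error rates of the real comparison. Of 50 genes changed at each size, 26, 44, 50 and 50 were recovered in the right direction for changes of 1.25, 1.5, 2 and 4-fold, and 6 of 15313 unchanged genes were called. Both lists shifted by 0.5 on the log2 scale were called, as was 1 of 18 lists that were not shifted.

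Lists, tests, alternatives and the rule for named genes were fixed before the data were examined, except where stated. Named genes are the 12 largest rises and 12 largest falls with a mean of at least 5 CPM, no overlap of the groups and a symbol that is not a clone or predicted gene, up to 4 called members of each list with a mean of at least 1 CPM, largest change first, and 16 genes chosen by name. The text gives the leading ones of each list, and 2 of the 12 largest falls are not reported here. Where a group held 20 counts or fewer, the ratio of counts may be given with a 95% exact binomial interval, and where it held 0, a lower bound with a floor of 3 counts over the group. Such intervals and floors cover counting error only. List medians were the same with such genes at their bound. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, edgeR's legacy dispersion, no filter (at least 1 count) or a stricter filter (1 CPM in 2 libraries), the replicate letter as a block, leaving out each library, a threshold of 0.1, a test against 1.5-fold and an estimated correlation. With 1 library left in a group, that library is assumed to vary like the other group. After the data were seen, 2 alternatives were added: removal of a loess trend (span 0.5, degree 1) of fold change with gene length and GC content through offsets, and leaving out mitochondrially encoded genes. GC content came from GENCODE M21 models for 99.9% of tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.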

Results

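RNA sequencing counts were analysed for 4 libraries of cells taken from Dll1-mCherry tumours of the MMTV-PyMT mouse, a transgenic model of mammary carcinoma, on the C57BL/6 strain. The cells are labelled primary mouse breast cancer-associated fibroblasts (CAFs), and a PDGFRa antibody was used to detect them in the digested tumours, per the labels' protocols. The labels do not state which fraction of the digested tumours was sequenced. The unirradiated CAF group and the irradiated CAF group, which received 6 Gy, held 2 libraries each, named A and B, and both are labelled day 6. The treatment label of the irradiated libraries places radiation at day 6, while the titles of all 4 libraries, unirradiated ones included, carry the same day. The time between radiation and collection is not stated in the labels. Total counts were 17569515 and 13011489 in unirradiated A and B and 15817969 and 23763830 in irradiated A and B. One count therefore corresponded to between 0.0421 and 0.0769 CPM, the count scaled to library size, in a library. Nothing states that A and B came from separate animals, so all p-values measure only the spread between these libraries, which may be technical. Levels are given as TMM-scaled CPM, mean ± SD with n = 2 libraries per group, and positions are on mm10.

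The comparison asked which transcripts differed between libraries of cells labelled CAFs from irradiated and unirradiated tumours. The homeobox gene Tlx1 (chromosome 19, 45150680 to 45156943) was the largest rise among named genes with a mean of at least 5 CPM, from 0.0703 ± 0.0150 CPM to 29.7 ± 0.902 CPM. Its counts summed to 2 in the unirradiated and 1237 in the irradiated group, a scaled ratio of 435 with a 95% counting interval of 120 to 3595. Csn2, encoding beta-casein (chromosome 5, 87692624 to 87699630), rose from 0.673 ± 0.192 to 139.5 ± 2.15 CPM (log2 fold change 7.73, SE 0.138). Csn1s2a, another casein gene (chromosome 5, 87774567 to 87788797), rose from 3 to 711 counts, a scaled ratio of 167 with an interval of 56.8 to 810, and Btn1a1, a milk fat globule protein, from 3.01 ± 1.40 to 99.5 ± 1.76 CPM. Col2a1, the type II collagen of cartilage (chromosome 15, 97975602 to 98004695), rose from 21.8 ± 1.35 to 1033 ± 6.12 CPM (log2 fold change 5.56, SE 0.0568). The other genes among the 12 largest rises were Sez6, Igha, Pi15, Fmn2, Fgb, B4galnt2 and Megf10, with log2 fold changes of 6.49, 6.33, 5.85, 5.49, 5.22, 5.14 and 5.06. Igha, an immunoglobulin constant gene, can share reads with related constant genes and is uncertain. Without unirradiated A the log2 fold changes of Sez6, Fmn2, Fgb, B4galnt2 and Btn1a1 became 7.56, 6.46, 6.75, 4.28 and 5.62, and without unirradiated B that of B4galnt2 became 6.47.

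Among the 12 largest falls, Notum, a secreted Wnt deacylase (chromosome 11, 120653788 to 120661175), fell from 12.4 ± 3.62 to 0.272 ± 0.129 CPM (log2 fold change -5.35, SE 0.331), and its log2 fold change was -5.99 without irradiated B. Nkd1 and Axin2, negative regulators of Wnt signalling, fell from 38.7 ± 1.73 to 2.45 ± 0.0679 CPM and from 63.3 ± 1.83 to 5.09 ± 0.734 CPM. Comp, a cartilage matrix protein, fell from 104 ± 3.22 to 6.13 ± 0.753 CPM. Spock2, Bcl11b, Gabra4, Slc25a34, Foxq1 and Aldh3b2 were also among the 12 largest falls, with log2 fold changes of -4.45, -4.07, -4.07, -3.99, -3.79 and -3.64.

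Of 15961 tested genes, 5409 were higher and 5184 were lower in the irradiated libraries at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 5368 did not pass. The changes exceeded 2-fold for 1721 higher and 1620 lower genes and 4-fold for 626 and 479. The spread between libraries of a group was small, with a common biological coefficient of variation of 3.86%, so that 4829 calls were of changes under 1.5-fold. Tested against a change of at least 1.5-fold, 2032 genes were higher and 1754 lower. DESeq2 called 4487 genes higher and 3421 lower.

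**Figure D1:**
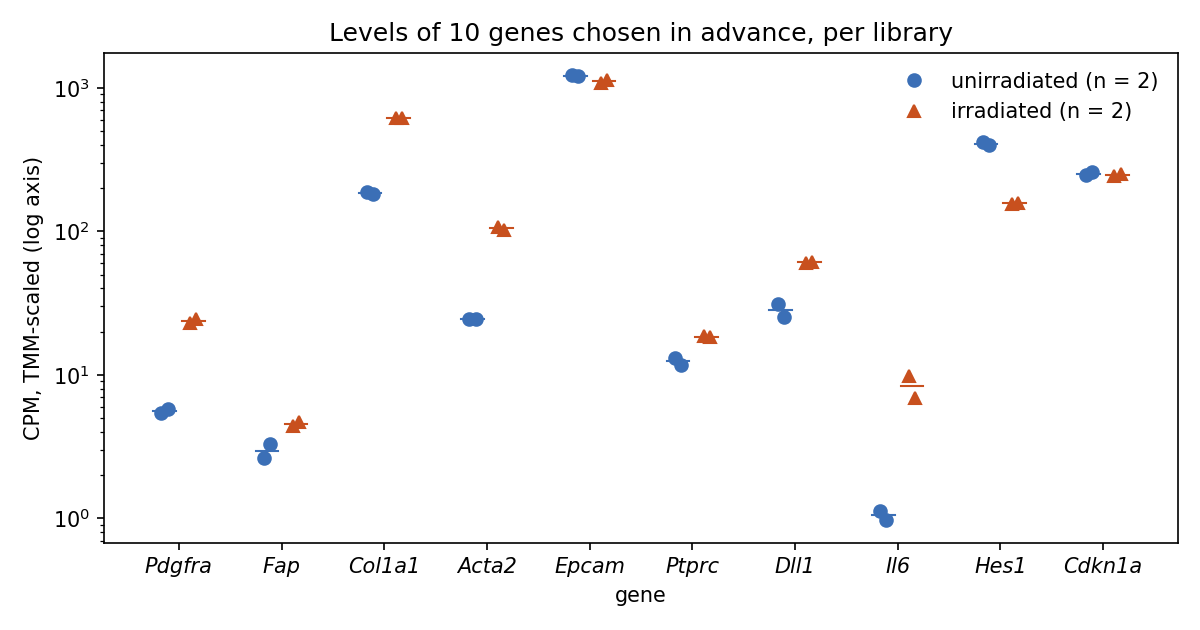
CPM on a log axis for 10 of the genes chosen in advance, with each point a library (circles unirradiated, triangles irradiated, n = 2 each) and each short line a group mean. Pdgfra averaged 5.59 CPM and Epcam 1211 CPM in the unirradiated libraries, against 23.7 and 1107 CPM in the irradiated ones.

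Fibroblast markers and matrix genes rose in the irradiated libraries. Pdgfra, the receptor that the antibody detects (chromosome 5, 75152292 to 75198215), rose from 5.59 ± 0.223 to 23.7 ± 1.17 CPM (log2 fold change 2.10, SE 0.140), Pdpn, encoding podoplanin, from 1.43 ± 0.422 to 33.3 ± 0.719 CPM, and the transcription factor Twist1 from 3.48 ± 0.568 to 38.3 ± 1.83 CPM. Of 17 tested fibroblast identity markers 15 were higher and 0 lower, with a median log2 fold change of 1.34. The exceptions were Pdgfrb (0.15) and Thy1 (0.03). Of 20 collagens 19 were higher and 1 lower, with a median of 1.47. Col1a1 (chromosome 11, 94936224 to 94953042) rose from 184 ± 5.24 to 616 ± 3.31 CPM, Col3a1 from 122 ± 9.47 to 509.5 ± 8.82 CPM and Col18a1 from 43.3 ± 0.882 to 245 ± 3.29 CPM. Of 26 matrix glycoproteins and proteoglycans 24 were higher and 1 lower (median 1.61), among them Fn1, encoding fibronectin, at 77.4 ± 3.65 and 401 ± 23.3 CPM. Of 27 matrix proteases, inhibitors and crosslinkers 21 were higher and 4 lower (median 1.08), led by the metalloproteinase inhibitor Timp3 at 36.8 ± 0.677 and 237 ± 4.29 CPM. Counts were the same adjusted over the list alone. The fibroblast identity list shares Col1a1, Col1a2 and Col3a1 with the collagens and Dcn, Lum and Mfap5 with the glycoproteins. It also shares Fap and Loxl1 with the proteases, so the 4 lists are not independent. By limma's camera with Benjamini-Hochberg adjustment, adjusted p was 8.71e-07, 1.27e-07, 1.26e-08 and 3.22e-05 for the 4 lists in this order. None of these calls held when camera estimated the correlation, with adjusted p = 0.213, adjusted p = 0.265, adjusted p = 0.213 and adjusted p = 0.213 with an estimated correlation. Fap, the fibroblast activation protein, was at 2.97 ± 0.490 and 4.54 ± 0.205 CPM (log2 fold change 0.64, adjusted p = 0.0187 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its call was lost without unirradiated A (0.46) and without irradiated B (0.60), with DESeq2 and after removal of a trend with gene length and GC content, with adjusted p between 0.0117 and 0.188 over its 13 alternatives.

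Epithelial transcripts were abundant in every library, although the cells are labelled CAFs. Changes in the response lists can therefore not be assigned to fibroblasts or to another cell type. The 28 tested epithelial and tumour cell markers summed to 22543 ± 8.23 CPM in the unirradiated and 18673 ± 504 CPM in the irradiated group, against 702 ± 31.4 and 2186 ± 15.6 CPM for the 17 fibroblast identity markers. Of these epithelial markers 9 were higher and 15 lower (9 and 16 adjusted over the list alone), and 12 were higher and 12 lower after removal of a trend with gene length and GC content. The median log2 fold change was -0.18 and camera's direction was down, while the mean was 0.27 (adjusted p = 0.272, camera with Benjamini-Hochberg adjustment). Csn2, Csn1s1 and the keratin Krt19 rose, with log2 fold changes of 7.73, 3.00 and 2.71, and the basal keratin Krt5 fell (-1.48). Epcam, an epithelial adhesion molecule (chromosome 17, 87635979 to 87651106), was at 1211 ± 14.1 and 1107 ± 31.1 CPM (log2 fold change -0.13, SE 0.0367). Its direction turned to 0.13 after removal of that trend, and its call was lost without unirradiated A (-0.12) and with no filter on low counts (-0.07).

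Markers of several other cell types moved with the fibroblast genes. Of 23 macrophage and monocyte markers 20 were higher and 0 lower (median 0.99), and their sum rose from 899 ± 16.4 to 1993 ± 57.4 CPM. Cd163, a scavenger receptor of macrophages, rose from 0.963 ± 0.0116 to 9.85 ± 1.04 CPM and Cd14 from 73.0 ± 4.72 to 297 ± 4.92 CPM. Of 21 endothelial markers 16 were higher and 0 lower (median 0.97), led by the VEGF receptors Kdr, from 4.29 ± 0.576 to 19.8 ± 0.394 CPM, and Flt1, from 13.9 ± 1.22 to 59.1 ± 5.51 CPM. In contrast, 9 of 15 T and NK cell markers were lower and 0 higher (median -1.54), among them Cd8a (-3.39) and Ctla4 (-2.18), though these genes together summed to only 25.9 ± 1.06 and 14.2 ± 0.476 CPM. Without irradiated B the log2 fold change of Cd8a was -4.93. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 9.70e-06 for macrophage, 1.42e-04 for endothelial and 0.00769 for T and NK markers, against adjusted p = 0.213, adjusted p = 0.213 and adjusted p = 0.265 with an estimated correlation. Ptprc, the pan-leukocyte gene, rose from 12.4 ± 0.985 to 18.5 ± 0.230 CPM (log2 fold change 0.56), a call lost after removal of the length and GC trend (0.23).

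Other marker lists did not pass camera's threshold. Higher and lower members numbered 5 and 1 of 8 for dendritic cells, with Ccr7 at -2.10 and Zbtb46 at 1.33, and 3 and 8 of 14 for neutrophils and mast cells. They numbered 2 and 6 of 10 for B and plasma cells, with Jchain at 2.94 and Igkc at 1.93 but Cd79a at -1.15. For pericytes and smooth muscle they numbered 8 and 2 of 14, with Steap4 at 1.48, and for skeletal muscle 1 and 4 of 7, with Mb, encoding myoglobin, at -1.68. They numbered 4 and 6 of 11 for Schwann cells and nerve, with Pmp22 at 2.15 and S100b at -1.48, and 2 and 5 of 7 for erythroid genes, with Hbb-bs at -3.02. For keratinocytes and skin they numbered 3 and 8 of 13, with Krt6b at -3.55. For adipocytes they numbered 5 and 4 of 14, with the uncoupling protein gene Ucp1 at -4.26 but Cidea at 1.76 and Cd36 at 1.52. All of these counts were the same adjusted over the list alone, and camera's adjusted p with Benjamini-Hochberg adjustment was 0.244, 0.710, 0.212, 0.103, 0.126, 0.786, 0.579, 0.103 and 0.555 in this order. The neutrophil list depended on single irradiated libraries. Its median of -0.86 became -1.84 without irradiated A, where camera's adjusted p was 0.0290 (range over 12 alternatives 0.0290 to 0.964), and -0.11 without irradiated B. Skeletal muscle markers passed without unirradiated A (0.0257) and without irradiated B (0.0393), within a range of 0.0257 to 0.446 over 11 alternatives. B and plasma cell, pericyte and keratinocyte markers passed with no filter on low counts, the last 2 also with a stricter filter. The Schwann cell markers had a median of -0.34 and a camera direction of down, while their mean was 5.77e-04. Ngp, a neutrophil granule gene, was at 9.74 CPM in irradiated A and 0.646 CPM in irradiated B, and its log2 fold change of -1.52 became -4.25 without irradiated A and -0.35, no longer past the threshold, without irradiated B. That of Hbb-bs became -4.45 without irradiated A and -2.05 without irradiated B. Globin, keratin 6 and immunoglobulin genes have near-identical copies and are uncertain.

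Genes listed as markers of CAF subtypes rose in all 3 lists. Of 22 inflammatory CAF markers 18 were higher and 3 lower (median 1.84), with the hyaluronan synthase Has1 rising from 0.522 ± 0.0630 to 9.72 ± 0.229 CPM, Efemp1 from 1.68 ± 0.261 to 15.5 ± 0.414 CPM and Dpt, encoding dermatopontin, from 3.30 ± 0.315 to 25.7 ± 0.951 CPM. The lower members were C4b (-1.42), Dpp4 (-0.48) and Cxcl12 (-0.39), which were singled out after their values were seen. Of 20 myofibroblast contractile genes 16 were higher and 0 lower (median 1.04), among them Tpm2, a tropomyosin, at 22.5 ± 1.84 and 165 ± 10.1 CPM and Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255336), at 24.4 ± 0.0667 and 105 ± 3.71 CPM (log2 fold change 2.11, SE 0.0729). All 8 tested antigen-presenting CAF markers were higher (median 0.88), including the class II genes Cd74 (1.15) and H2-Aa (0.94) beside Krt19 (2.71) and Slpi (1.64). Class II genes are also expressed by macrophages and Krt19 by epithelium, whose markers are described above. Counts were the same adjusted over the list alone. Adjusted p was 4.42e-05, 7.27e-06 and 4.48e-04 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.213, adjusted p = 0.376 and adjusted p = 0.445 with an estimated correlation.

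Cytokine and growth factor transcripts rose. Il6 (chromosome 5, 30013114 to 30019981) rose from 1.05 ± 0.115 to 8.40 ± 2.07 CPM (log2 fold change 2.93, SE 0.287), and the monocyte chemokines Ccl2 and Ccl7 rose from 12.3 ± 0.391 to 121 ± 0.987 CPM and from 1.64 ± 1.06 to 24.5 ± 0.523 CPM. Without unirradiated A the log2 fold change of Ccl7 was 4.78 in place of 3.80. Of 25 inflammatory cytokines and chemokines 21 were higher and 1 lower (21 and 2 adjusted over the list alone), with a median of 1.32. Of 18 NF-kB target genes 14 were higher and 3 lower (median 0.67), with Tnfaip2 at 10.1 ± 1.28 and 91.1 ± 0.898 CPM and the adhesion molecule Vcam1 at 3.30 ± 0.315 and 28.8 ± 0.812 CPM. Of 27 growth and angiogenic factors 17 were higher and 6 lower (median 0.93), including Pdgfb (1.69) and Vegfc (1.61). Camera with Benjamini-Hochberg adjustment gave adjusted p of 8.83e-06, 5.67e-04 and 0.0157 for these lists, and adjusted p = 0.222, adjusted p = 0.376 and adjusted p = 0.452 with an estimated correlation. Macrophage markers rose in the same libraries, as given above. Receptors and targets of IL-6 and STAT3 were 15 higher and 7 lower of 22 (median 0.39, camera adjusted p = 0.205), with the co-receptor Il6st higher (1.03) and the feedback inhibitor Socs1 lower (-1.56), and this list passed with no filter on low counts. The counts of the NF-kB, growth factor and IL-6 lists were the same adjusted over the list alone.

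Interferon-stimulated and MHC class I genes fell. Oas2, an antiviral oligoadenylate synthetase (chromosome 5, 120730333 to 120749853), fell from 172 ± 0.486 to 33.7 ± 1.36 CPM (log2 fold change -2.36, SE 0.0614), Mx1 from 40.9 ± 2.05 to 9.21 ± 0.781 CPM and Usp18 from 57.6 ± 2.61 to 18.1 ± 1.06 CPM. Of 28 type I interferon response genes 26 were lower and 0 higher (median -0.88). Of 20 genes of MHC class I presentation 16 were lower and 3 higher (median -0.82). Nlrc5, a transactivator of class I genes, fell from 62.5 ± 0.524 to 15.8 ± 0.256 CPM and H2-T23 from 455 ± 30.3 to 158 ± 12.6 CPM. H2-Q6 (-2.05) and H2-Q7 (-1.95) are near-identical, so their separate values are uncertain. The higher members were Erap1 (0.70), Tapbp (0.41) and Tap2 (0.17), singled out after their values were seen. Counts were the same adjusted over the list alone, and camera with Benjamini-Hochberg adjustment gave adjusted p of 1.26e-08 and 2.46e-04, against adjusted p = 0.213 and adjusted p = 0.445 with an estimated correlation. T and NK cell markers fell in the same libraries and macrophage markers rose.

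**Figure D2:**
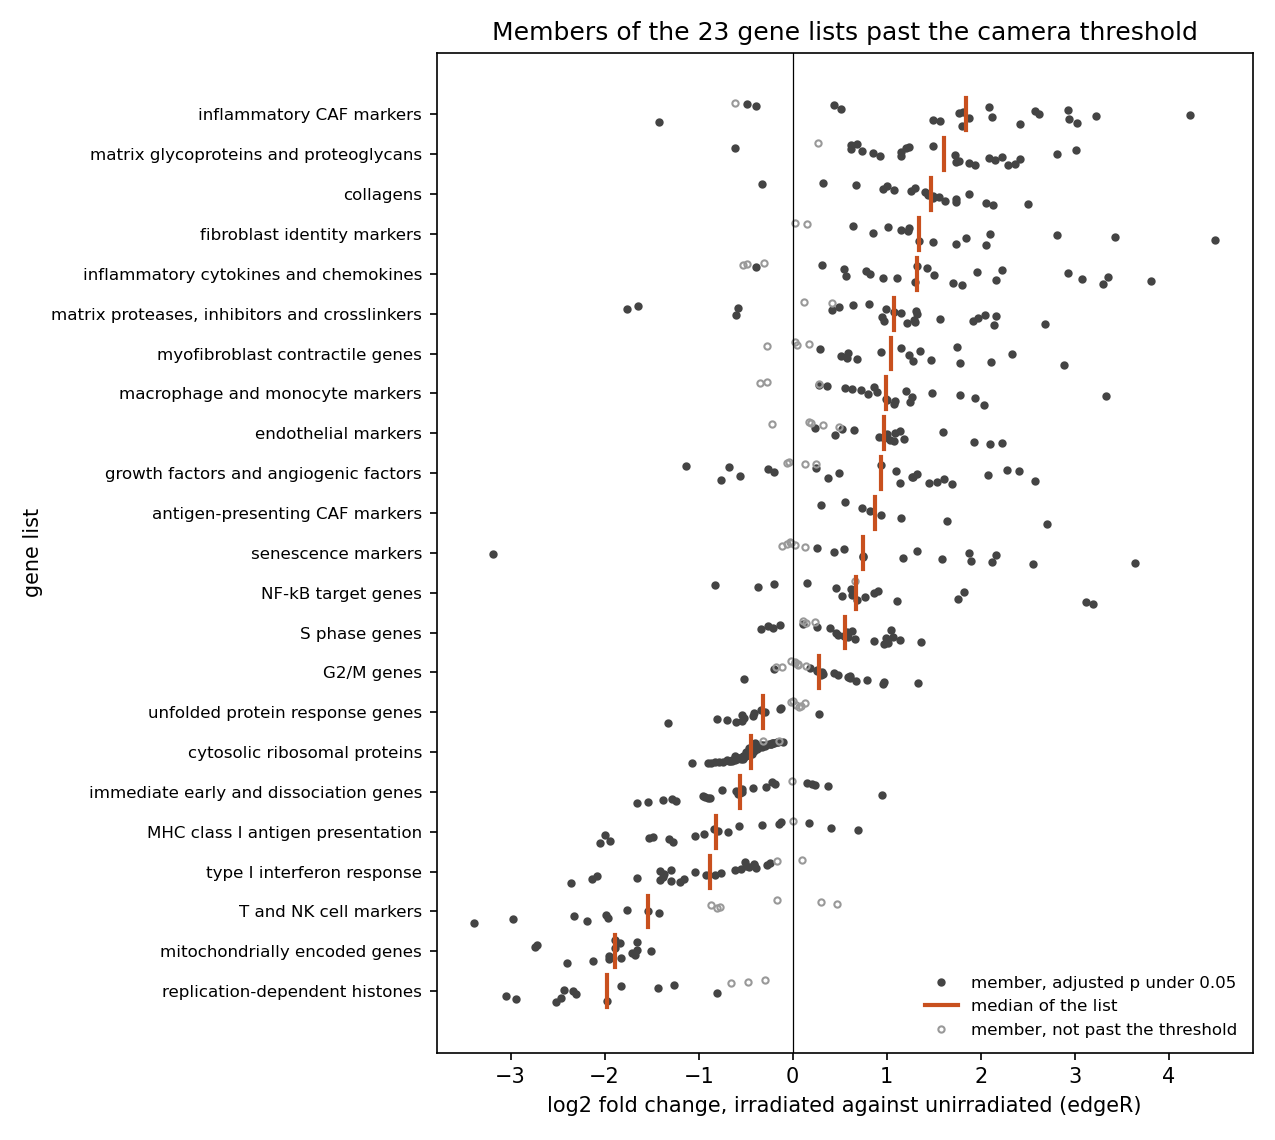
Log2 fold change (irradiated against unirradiated) of each tested member of the 23 gene lists past camera's threshold, with the list median as a bar. Filled points passed edgeR's threshold and open points did not. Medians run from 1.84 for inflammatory CAF markers to -1.97 for histones, and no list kept its call with an estimated correlation.

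Target genes of p53 moved both ways. Cdkn1a, encoding the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), was at 251 ± 8.71 and 248 ± 4.63 CPM (log2 fold change -0.02, SE 0.0457, adjusted p = 0.744 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mdm2, the p53 ubiquitin ligase, rose from 92.9 ± 1.86 to 127 ± 3.07 CPM (log2 fold change 0.45, SE 0.0555), and the death receptor gene Tnfrsf10b rose from 19.6 ± 0.431 to 41.9 ± 0.238 CPM. Of 29 p53 target genes 16 were higher and 6 lower (median 0.27, camera adjusted p = 0.0523). The list passed without irradiated B (0.0401), after removal of the length and GC trend (0.0414), with the replicate block and with no filter on low counts, within a range of 0.00505 to 0.367 over 12 alternatives. Of 26 genes of double-strand break repair 11 were higher and 5 lower (median 0.13, camera adjusted p = 0.157), with Brca1 at 11.4 ± 1.01 and 31.0 ± 1.01 CPM, and this list passed with no filter. After removal of the length and GC trend the repair list had 8 genes higher and 6 lower (median 0.01, camera adjusted p = 0.755). Counts of both lists were the same adjusted over the list alone.

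Cell cycle genes were higher on balance. Of 26 S phase genes 19 were higher and 4 lower (median 0.56), with Dtl rising from 19.7 ± 0.458 to 50.8 ± 0.980 CPM and the transcription factor E2f1 from 19.8 ± 1.93 to 43.9 ± 3.65 CPM. Of 26 G2/M genes 16 were higher and 2 lower (median 0.28), with the cytokinesis gene Anln rising from 30.3 ± 1.49 to 77.1 ± 5.80 CPM and Top2a from 117 ± 0.122 to 228 ± 12.5 CPM. Of 21 senescence markers 14 were higher and 1 lower (median 0.74), led by the insulin-like growth factor binding proteins Igfbp2, from 25.1 ± 1.44 to 310.1 ± 18.9 CPM, and Igfbp5, from 1115 ± 3.56 to 6572 ± 295 CPM. Hmga2, a chromatin protein, fell (-3.19), and the cell cycle inhibitors Cdkn1a, Cdkn1b, Cdkn2a and Cdkn2b did not pass the test. Counts were the same adjusted over the list alone. Camera with Benjamini-Hochberg adjustment gave adjusted p of 4.31e-04, 0.00857 and 5.67e-04 for these 3 lists, and adjusted p = 0.213, adjusted p = 0.445 and adjusted p = 0.213 with an estimated correlation.

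Notch genes moved both ways. Dll1, the ligand by which the tumours are labelled (chromosome 17, 15367354 to 15376872), rose from 28.3 ± 4.04 to 60.7 ± 0.501 CPM (log2 fold change 1.08, SE 0.0801). Notch2 (1.03), Notch3 (0.86), Jag1 (0.53) and the target Heyl (1.29) rose, while the target Hes1 (chromosome 16, 30064384 to 30067796) fell from 407 ± 12.5 to 156 ± 2.52 CPM (log2 fold change -1.38, SE 0.0456). Notch1 (-0.18) and Hey1 (-0.14) passed by small amounts. Notch1 lost its call without irradiated B (-0.08), with DESeq2 and with no filter. Hey1 lost its call whichever library was left out (-0.15 to -0.11), and it passed in only 6 of its 13 alternatives. Of 24 Notch genes 10 were higher and 8 lower (median 0.18, camera adjusted p = 0.555). Of 28 Wnt ligands, antagonists and targets 12 were higher and 12 lower, and the median (-0.24) and camera's direction (down) differed in sign from the mean (0.24, adjusted p = 0.896). Rspo3, a secreted Wnt agonist, had 0 counts in the unirradiated and 159 in the irradiated group, at least 37.3-fold higher with a floor of 3 counts over the group, and Rspo1 rose from 7 to 146 counts. Without unirradiated A and without unirradiated B the log2 fold change of Rspo1 was 3.10 and 4.82 in place of 3.83. Of 19 genes of TGF-beta signalling 8 were higher and 6 lower (median 0.03, camera adjusted p = 0.579), with Ctgf, encoding a matricellular protein, at 164 ± 0.114 and 639 ± 2.37 CPM. Counts of these 3 lists were the same adjusted over the list alone.

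Several metabolic and stress genes fell. Xbp1, a transcription factor of the unfolded protein response (chromosome 11, 5520659 to 5525893), fell from 1234 ± 14.9 to 492 ± 9.72 CPM, the chaperone Hspa5 fell with a log2 fold change of -0.61, and of 20 genes of that response 13 were lower and 1 higher (median -0.32). The list's call (camera adjusted p = 0.0157, adjusted p = 0.446 with an estimated correlation) was also lost without irradiated A (0.0585) and after removal of the length and GC trend (0.105), within a range of 0.0110 to 0.446 over 12 alternatives. After that removal 11 of its genes were lower and 6 higher. Of 25 immediate early and dissociation genes, which tissue digestion can induce, 19 were lower and 5 higher (median -0.56), and their sum went from 36299 ± 821 to 22430 ± 448 CPM. Jun fell from 4270 ± 158 to 1356 ± 29.3 CPM and Klf4 from 647 ± 5.07 to 223 ± 4.05 CPM (camera adjusted p = 4.31e-04, adjusted p = 0.446 with an estimated correlation). Of 27 glycolysis and hypoxia genes 6 were higher and 16 lower, or 7 and 17 adjusted over the list alone (median -0.20, camera adjusted p = 0.169), with Pfkfb3 higher (1.67) and Eno1 (-1.17) and Hk2 (-1.16) lower. Of 26 NRF2 and antioxidant genes 6 were higher and 12 lower (median -0.07, camera adjusted p = 0.432), with Gpx3 at 1.84 and Gsta4 at -1.84, and after removal of the length and GC trend 11 were higher and 9 lower. Counts of the other lists were the same adjusted over the list alone.

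Mitochondrial, ribosomal protein and histone transcripts were lower in the irradiated libraries. Mitochondrially encoded genes took 10.6% and 10.7% of counts in unirradiated A and B and 3.03% and 2.97% in irradiated A and B. All 15 tested members fell (median -1.89), including the ribosomal RNA mt-Rnr2 from 29854 ± 229 to 5654 ± 62.2 CPM. Of 70 cytosolic ribosomal protein genes 68 were lower and 0 higher (median -0.45), with Rpl22 at -1.08. Of 15 replication-dependent histones, whose transcripts mostly but not always lack a poly(A) tail, 12 were lower and 0 higher (median -1.97), with Hist1h1c falling from 405 ± 1.78 to 70.0 ± 6.24 CPM. Whether the histone transcripts read here carried a tail was not tested. Counts were the same adjusted over the list alone. Camera with Benjamini-Hochberg adjustment gave adjusted p of 4.32e-08, 7.95e-12 and 3.22e-05, and adjusted p = 0.213, adjusted p = 0.446 and adjusted p = 0.213 with an estimated correlation. Fold changes also followed gene length across genes, with Spearman's rho of 0.313 for length over 15961 genes and -0.119 for GC content over 15945 genes. Genes are not independent replicates. After that trend was removed the ribosomal protein median was -0.18, with 47 genes lower and 4 higher.

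**Figure D3:**
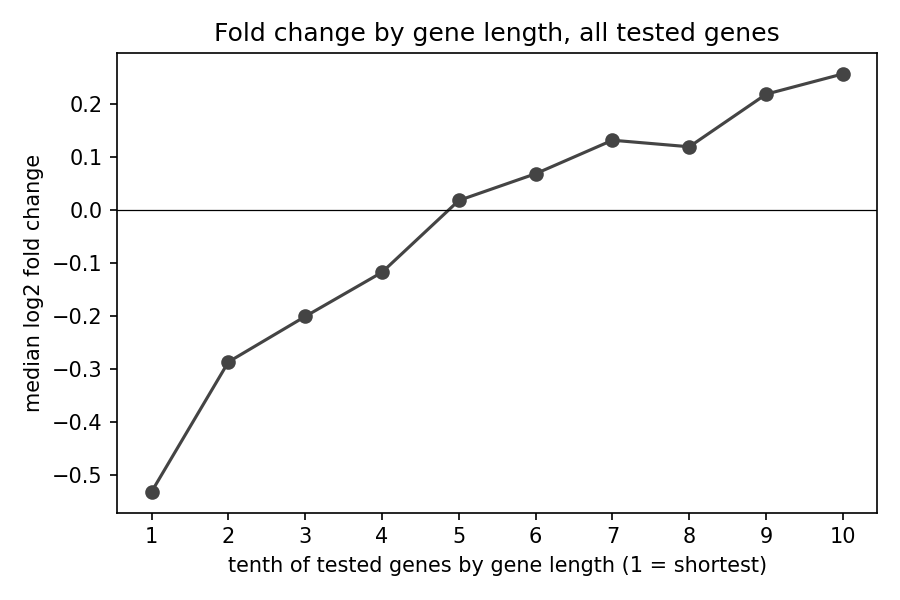
Median log2 fold change (irradiated against unirradiated) of all tested genes in 10 groups of increasing gene length. It was -0.53 in the shortest group (56 to 1246 bases) and 0.26 in the longest (9356 to 123179 bases).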

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

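The alternatives with the length and GC trend removed and with mitochondrially encoded genes left out were chosen after the data were seen. Counts of higher genes lay between 4487 and 5855 and of lower genes between 3421 and 5632 over the alternatives, apart from the test against 1.5-fold, which gave 2032 and 1754 because it asks for larger changes. DESeq2 called 3421 genes lower, and the cause was not tested. Leaving out 1 library gave 4935 to 5188 higher and 4457 to 4728 lower genes. Removing the length and GC trend gave 5103 and 4840, with 8590 of 10593 calls kept in direction and 73 turned, among them Epcam (0.13). Between 15 and 19 lists were higher and between 7 and 10 lower, except with an estimated correlation, where 0 were higher and 0 lower. That setting rests on 2 residual degrees of freedom and had little power. How much of the loss came from correlation among genes was not tested. Leaving out mitochondrially encoded genes removed their own list. Of 191 named genes, 178 kept their side of the threshold with DESeq2 and 13 lost it, 184 with the trend removed, and 191 with RLE, upper-quartile scaling or the block. The letters A and B were not taken to pair the libraries: deviations of the groups' A and B correlated at 0.0116 over 15961 genes, and nothing in the labels ties them. These deviations hold much counting noise, so a weak pairing could be missed. With the replicate block 5418 genes were higher and 5200 lower, 16 lists were higher and 8 lower, and the p53 list passed (adjusted p 0.0459). Depth limits genes near 1 count, where 1 count is 0.0421 to 0.0769 CPM.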

Other observations

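The genes of this paragraph were listed after the data were seen, so their counts describe these libraries and test nothing. Of 13 tested feedback targets of Wnt and beta-catenin 12 were lower and 0 higher, among them Wif1 (106 ± 1.99 to 17.3 ± 0.406 CPM), Apcdd1 (64.9 ± 2.78 to 7.25 ± 0.209 CPM) and Nkd2 (105 ± 2.05 to 32.8 ± 0.816 CPM), while Lgr5 was at 2.21 ± 0.498 and 2.88 ± 0.0155 CPM. Of 13 tested cartilage matrix genes 10 were higher and 3 lower. Cnmd, encoding chondromodulin, rose from 1.81 ± 0.389 to 45.0 ± 4.37 CPM, Chil1 from 44.8 ± 0.0147 to 575 ± 0.0822 CPM and Col9a1 from 282 ± 1.75 to 742 ± 0.824 CPM, while Comp and the transcription factors Sox9 (-0.62) and Sox5 (-1.15) fell. Of 13 milk protein and secretory genes 8 were higher and 2 lower: Csn1s1 rose from 30.2 ± 2.77 to 240.1 ± 5.06 CPM, while Csn3, the most abundant of them, fell from 5791 ± 48.7 to 3203 ± 102 CPM. Of 10 target genes of YAP and TEAD 9 were higher and 0 lower, with Ankrd1 at 1.41 ± 0.0596 and 23.4 ± 0.207 CPM.

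In the 3 paragraphs that follow, the tests of a fibroblast share, an epithelial share, poly(A) carry-over and leukocyte number were chosen after the results were seen. Those of gene length and GC content were added after the data were seen, with bounds set before their own outcomes were known. Fibroblast and matrix genes were higher in the irradiated libraries. A trend with gene length and GC content is argued against as the whole cause, since the median log2 fold change of the 57 members was 1.44 before and 1.26 after its removal (95% bootstrap interval 1.11 to 1.58). The bootstrap intervals in these 3 paragraphs resample list members, which are not independent replicates. They hold no spread between libraries or animals. A lower share of epithelial cells that raises every other cell type was tested with the T and NK markers, whose median was -1.54 (-2.18 to -0.81). It stays open, because these markers summed to only 25.9 and 14.2 CPM and a separate loss of T and NK cells would hide such a rise. Macrophage and endothelial markers rose beside the fibroblast markers, with medians of 0.99 and 0.97. A larger share of the same fibroblasts stays open and may act beside a change within them: 41.2% of the 17 fibroblast markers lay more than 0.5 log2 and 3 standard errors from the list median, between the 25% and 50% bounds set for the test, and irradiation itself was not separated from cell makeup.

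Mitochondrial, ribosomal protein and histone transcripts were lower in the irradiated libraries, and for mitochondrial ones the length and GC trend is argued against as the whole cause, with a median of -1.41 after its removal (-1.62 to -1.24, before -1.89). For histones the trend stays open (-1.59, interval -2.19 to -0.65, before -1.97), since the interval spans 50% of the earlier size, the bound set for the test. After removal 9 members were lower and 0 higher, with a camera adjusted p of 6.31e-04 (range over 12 alternatives 1.51e-07 to 0.213). That value compares the histones with other genes and does not measure how much of the fall the trend explains. For ribosomal protein genes the trend also stays open, since the median after removal (-0.18, interval -0.23 to -0.15, before -0.45) was under 50% of the earlier size. After removal the list still passed camera with the preset correlation. Before removal it did not pass with an estimated correlation (camera adjusted p = 0.446). Less carry-over of RNA without a poly(A) tail, other differences in RNA handling between the groups and irradiation also stay open and were not separated. The polyadenylated ribosomal protein genes had a median of -0.45 (-0.47 to -0.42), but -0.18 without the trend, and small noncoding RNA genes had a median of -0.83 (-1.13 to -0.50) over 61 genes, between the bounds set for the histones. The value for small noncoding RNA genes is before removal of the trend. All tested genes of the shortest group (56 to 1246 bases) had a median of -0.53.

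Interferon and MHC class I genes were lower in the irradiated libraries. Macrophage and monocyte markers did not fall with these genes, with a median of 0.99 (0.62 to 1.20). Among them the pan-leukocyte gene Ptprc had a log2 fold change of 0.56, a call lost after removal of the length and GC trend (0.23). The rise of these markers was known when the test of fewer leukocytes of all kinds was chosen. It therefore describes these libraries and does not test that explanation. The length and GC trend is argued against as the whole cause, with a median of -0.77 after its removal (-0.94 to -0.55, before -0.84) over 48 members. A lower number of T and NK cells, a difference between tumours and irradiation itself may each contribute and were not separated.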
